A study of Arabidopsis thaliana with 27 samples.

How the data were processed

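Transcript levels were measured in leaves of 4-week-old Arabidopsis thaliana on 27 one-colour arrays of 576 probes each. Per the labels' protocols, plants grew at 9 per pot, 22 °C, 75% humidity and a day length of 12 h. Leaves were infiltrated with a bacterial suspension through a needle-less syringe. Total RNA was amplified and labelled with 1 fluorescent dye. Each sample pooled 2 leaves per plant from 3 pots, and the labels number 3 experiments (sets 1 to 3) that are called biological replicates. The log2 values were taken as deposited in the series' value table. The base of the logarithm is not given in the sources used here: base 2 was read from the values, which run from 0.66 to 11.4 with no negative value, as the log2 brightness of a scanner would. If the base were another, every difference below would scale by 1 factor and no test would change. The scanner, the background correction and the normalization are not given in the sources used here. Of all values, 15.8% occur on more than 1 array, and array medians differ by up to 0.63.

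The median over all probes stood at 4.27 and 4.21 for wild type (Col-0) with hrcC bacteria at 9 h in sets 1 and 2, at 4.11 and 4.14 for the cbp60g cbp60h mutant, at 4.11 and 4.12 for pad4-1, and at 3.90 and 4.01 for the cbp60g cbp60h pad4 mutant. For cbp60h it was 4.17, 4.23 and 4.39 in sets 1 to 3. With Psm at 24 h the medians of sets 1 to 3 were 4.48, 4.44 and 4.41 (Col-0), 4.53, 4.51 and 4.50 (cbp60g cbp60h), 4.46, 4.47 and 4.48 (pad4-1), and 4.07, 4.38 and 4.23 (cbp60g cbp60h pad4). The set 3 arrays labelled hrcC 24 h had medians of 4.12 (Col-0), 4.09 (cbp60g cbp60h), 4.15 (pad4-1) and 3.94 (cbp60g cbp60h pad4). The table gives no signal over background and no count, so the number of arrays limits the precision.

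Probes were named from the platform annotation, which can be old. It gave a single gene for 181 probes, several for 0, and none for 395, which are unnamed here. All 181 names matched the reference gene table (assembly TAIR10.1, used for names only), 133 as locus codes and 48 as symbols. Each name belongs to 1 probe. The 181 named genes were tested, and all 576 probes entered an additional fit. The probes of CBP60g, CBP60h (also called SARD1) and PAD4 are not among the named ones, so the genotypes in the labels were not checked here.

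Groups followed the labels. The 23 arrays of the 9 groups with 2 or 3 arrays entered 1 group-means model in limma 3.58.1 (R 4.3.3, lmFit and eBayes), without a block, so that all groups share 1 estimate of the spread. Tests were two-sided with Benjamini-Hochberg adjustment over the 181 genes, and an adjusted p under 0.05 was called. In all 19 comparisons were made: mutants against Col-0 and against each other within a treatment, the departure from additive effects under Psm, the difference of each mutant's effect between treatments, and Col-0 between treatments. Bacterial strain and time differ together between the treatments. The 4 arrays labelled hrcC 24 h have no replicate and entered no test of these. Every p printed with a gene is an adjusted p from limma.

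In simulated data with the arrays' own spread and 45 of 181 genes changed (20 repeats), the test of the cbp60g cbp60h mutant against Col-0 under hrcC recovered 14.3%, 59.7% and 93.3% of changes of 0.5, 1 and 2 on the log2 scale, with 2.71% of calls false. Under Psm the same test recovered 20.7%, 69.7% and 98.3%, with 4.07% false. The test of non-additive effects recovered 5.67%, 43% and 86.7%, with 4.25% false. The noise was drawn independently for each gene and array, without a set effect, so these shares can differ in the real data. They also hold for that number of changed genes only.

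Genes were named by a rule written before the data were examined. For each mutant against Col-0 these are up to 8 called genes with the largest rises and 8 with the largest falls whose arrays do not overlap between the groups, and for other comparisons up to 5 each way. Members of the fixed gene lists are given beside them. A gene named outside the rule is marked as chosen after its values were seen.

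Before the data were examined, 14 gene lists with 229 genes were fixed. Only 10 of these genes were measured: UGT76B1 (salicylic acid synthesis and its regulators), WRKY53 and GRX480 (salicylic acid response), AT2G04400 (tryptophan and camalexin), PDF1.2 (ethylene and jasmonate-ethylene defence), COR47 (abscisic acid, cold and dehydration), WRKY22 and WRKY29 (pattern-triggered response), BIP1 (endoplasmic reticulum folding) and AT5G60390 (housekeeping). The lists of targeted genes, the CBP60 family, jasmonate, photosynthesis, oxidative stress and senescence, and other cell types of the leaf had 0 measured members. No list reached the 5 members needed for a gene set test, so these members are given as counts, over all genes and adjusted over the list alone. Groups by gene family were written after values had been seen; those of 5 or more members were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry.

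The set number pairs samples because the labels call each set 1 experiment. Over 82 pairs of arrays from the same set, deviations from the group means correlated at 0.14 on average (range -0.24 to 0.62, 47 pairs over 0.1). For arrays of different sets the average was -0.076. Deviations cancel within a group, so this value tends to the opposite sign and is no separate comparison. Between groups of 2 arrays the same value occurs in both sets, so the 82 pairs are not independent. The same-set average was 0.187 over the 62 pairs without cbp60h (41 over 0.1). It was 0.000695 over the 20 pairs with a cbp60h array (6 over 0.1, range -0.24 to 0.43). This average cannot exclude pairing of the cbp60h arrays by set. Their arrays of sets 1 and 2 were close, while deviations in a group of 2 arrays are opposite, so such values can offset each other. Of the 19 pairs of replicates, the cbp60h arrays of sets 1 and 2 lay closest, with a root mean square difference of 0.24 (r = 0.991 across probes), against 0.44 for the next pair and 0.83 for the farthest. No 2 arrays were identical, and the pair was also averaged and counted as 1 replicate in an alternative.

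Alternatives fixed before the data were examined were the set as a replicate block, median re-centring, quantile normalization, leaving out the dimmest 25% of genes, an intensity trend with robust moderation, adding the set 3 hrcC 24 h arrays to the hrcC groups with or without the block, fitting only the groups compared, and leaving out each array in turn. Alternatives chosen after seeing the data were the fit of all probes and centring on 14 basal genes. Averaging the close cbp60h pair, leaving out the cbp60h arrays, and the family groups were also chosen then. Centring gave each array the same median level over the 14 genes but did not hold their differences level. Between the triple mutant and Col-0 under Psm it moved their median difference from -0.0867 to -0.211. Unnamed probes were left out of the gene accounts because no gene can be given for them here.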

Results

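Transcript levels of 181 named genes were compared in leaves of wild-type Arabidopsis (Col-0) and of 4 mutant lines on 27 small arrays. CBP60g and CBP60h (SARD1) are related transcription factors that act in salicylic acid signaling, and PAD4 is a lipase-like regulator of the same defence pathway. The lines were cbp60h, the cbp60g cbp60h double mutant, pad4-1 and the cbp60g cbp60h pad4 triple mutant. Leaves received hrcC, a Pseudomonas syringae pv. tomato DC3000 strain without a working type III secretion system, or the strain that the labels call Psm. At 9 h after hrcC there were 2 arrays each of Col-0, the double mutant, pad4-1 and the triple mutant, and 3 of cbp60h. At 24 h after Psm there were 3 arrays each of Col-0, the double mutant, pad4-1 and the triple mutant. Set 3 also held 1 array of each of these 4 genotypes labelled hrcC 24 h. Values are log2 brightness as read from the deposited table, and a difference of 1 stands for a 2-fold change if the base of the logarithm is 2. According to its title, the study asked how far CBP60g and CBP60h can stand in for each other in salicylic acid signaling.

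In Col-0, leaves with Psm at 24 h differed from leaves with hrcC at 9 h by large steps in both directions. AT1G09500, an alcohol dehydrogenase-like gene, was higher by 4.64 (SE 0.60, adjusted p = 1.54e-05), at 6.83 ± 0.48 (SD, n = 3) against 2.18 ± 0.27 (SD, n = 2). AT3G59930 was higher by 3.32 (SE 0.76), AT2G32150 by 3.09 (SE 0.42), AT1G76960 by 2.62 (SE 0.52) and the chitinase gene CHI (AT2G43570) by 2.56 (SE 0.32). The largest fall was that of another chitinase gene, AT2G43620, which fell by 5.16 (SE 0.41, adjusted p = 3.55e-08), from 9.71 ± 1.34 (SD, n = 2) to 4.55 ± 0.26 (SD, n = 3). AT5G64120, a peroxidase gene, fell by 3.62 (SE 0.32), the protease inhibitor gene AT2G38870 by 2.51 (SE 0.53) and the beta-tubulin gene TUB6 (AT5G12250) by 1.90 (SE 0.27). The plant defensin gene PDF1.2 (AT5G44420) fell by 2.98 (SE 0.76, adjusted p = 0.00495), but without Col-0 hrcC replicate 1 the difference was -1.71 (adjusted p = 0.123). Of the 10 measured members of the fixed lists, 5 changed both over all genes and adjusted over the list alone: GRX480 (AT1G28480), a glutaredoxin gene of the salicylic acid response, rose by 1.16, while PDF1.2, WRKY29 (AT4G23550), the ER chaperone gene BIP1 (AT5G28540) and the elongation factor gene AT5G60390 fell. Without Col-0 hrcC replicate 2 AT1G76960 differed by 1.71, and GRX480, BIP1 and AT5G60390 lost their calls, at 0.77, -0.84 and -0.71. BIP1 also lost its call without Col-0 hrcC replicate 1 (-1.19), both BIP1 and AT5G60390 did so without Col-0 Psm replicate 1 (-0.86 and -1.10), and AT5G60390 differed by -2.26 without Col-0 hrcC replicate 1. In all, limma called 60 of 181 genes, 41 higher and 19 lower. This split was 30 and 34 after quantile normalization and 82 and 8 after centring on 14 basal genes. That centring moved the median difference of the 14 genes themselves from -0.0892 to 0.415, so it may have added rises of its own. Strain and time changed together here, so the comparison separates neither.

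Under Psm, the double mutant had higher levels than Col-0 of 7 genes and lower levels of 5, WRKY53 among them. AT4G17470, an alpha/beta hydrolase gene, rose by 2.67 (SE 0.30, adjusted p = 6.64e-06), from 4.76 ± 0.63 to 7.44 ± 0.17 (SD, n = 3 each). AT4G24340 rose by 1.99 (SE 0.29) and its neighbour AT4G24350 by 1.32 (SE 0.32), both of the phosphorylase superfamily, and the GDSL lipase-like gene AT1G54010 rose by 1.83 (SE 0.24). WRKY53 (AT4G23810), a transcription factor gene of the fixed salicylic acid response list, fell by 1.61 (SE 0.27, adjusted p = 0.000564), from 4.74 ± 0.16 to 3.13 ± 0.19 (SD, n = 3 each). The C2-domain gene AT4G00700 fell by 1.08 (SE 0.19), CCL (AT3G26740) by 1.24 (SE 0.30) and ATPMEPCRB (AT4G02330) by 0.78 (SE 0.19). AT2G14290, AT1G11050 and AT5G21105 were higher by 0.98, 0.84 and 0.61, and CHI was lower, with a difference of -0.97 (adjusted p = 0.0453). WRKY53 was the 1 list member of 10 that changed, over all genes and adjusted over the list alone: GRX480 differed by 0.15 (SE 0.28, adjusted p = 0.882) and UGT76B1 by -0.57 (SE 0.44, adjusted p = 0.533). The 12 calls were 7 higher and 5 lower (4 and 6 after quantile normalization or median re-centring, 4 and 9 after centring on basal genes), and there were 7 without Col-0 replicate 1 or Col-0 replicate 3. The rise of AT4G24350 was no longer called under any of those scalings (1.15, 1.16 and 1.14), nor were those of AT1G11050 and AT5G21105. Apart from left-out arrays, CHI lost its call in 5 of 11 alternatives, ATPMEPCRB in 3 of 10 and AT2G14290 in 1 of 10. AT4G17470, AT4G24340, AT1G54010, WRKY53 and AT4G00700 kept their calls without each of the 6 arrays and in every alternative in which they were tested (11, and 10 for AT4G00700, which the filter on dim genes removed). CHI, AT1G11050 and AT5G21105 lost theirs without any 1 of 5 arrays, Col-0 replicates 1, 2 and 3 (CHI at -0.97, -0.96 and -0.99) and double mutant replicates 1 and 3 (CHI at -0.99 and -0.76). CCL lost its call without Col-0 replicate 1 (-1.13) or 3 (-1.10), ATPMEPCRB without Col-0 replicate 1 (-0.67) or 2 (-0.76) or double mutant replicate 3 (-0.67), AT4G24350 without Col-0 replicate 1 (1.15) and AT2G14290 without Col-0 replicate 3 (0.68).

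In pad4-1 under Psm, AT4G17470 and AT1G54010 were again higher than in Col-0. AT4G17470 rose by 2.53 (SE 0.30, adjusted p = 7.33e-06), to 7.30 ± 0.49 (SD, n = 3), and AT1G54010 by 2.05 (SE 0.24), to 5.33 ± 0.30 (SD, n = 3). AT4G00700 fell by 1.04 (SE 0.19, adjusted p = 0.00185). AT5G39670, which encodes a calcium-binding EF-hand protein, fell by 1.71 (SE 0.41, adjusted p = 0.0243), from 6.87 ± 0.51 to 5.16 ± 0.66 (SD, n = 3 each), and AT4G25900 fell by 0.98 (SE 0.26, adjusted p = 0.0486). None of the 10 list members passed the limma test, over all genes or adjusted over the list alone: WRKY53 differed by -0.80 (SE 0.27, adjusted p = 0.12) and PDF1.2 by 1.00 (SE 0.68). The 5 calls, 2 higher and 3 lower (2 and 5 after quantile normalization or median re-centring, 2 and 21 after centring on basal genes), were 3 without Col-0 replicate 1, Col-0 replicate 3 or pad4-1 replicate 2. AT5G39670 was not called without those arrays, at -1.57, -1.55 and -1.39, or without pad4-1 replicate 3, at -1.68. The change of AT4G25900 was not called with the set as a block (adjusted p = 0.0565), nor without Col-0 replicates 1, 2 or 3 (-0.84, -1.08 and -1.01) or pad4-1 replicates 1 or 2 (-1.05 and -0.76).

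The double mutant and pad4-1 shared 3 of their calls under Psm, AT4G17470 and AT1G54010 higher and AT4G00700 lower, with 0 in opposite directions. Independent lists of these sizes would share 0.0773 higher and 0.0829 lower. In 100 simulations every group, Col-0 included, was drawn without a change, and both comparisons used the same simulated Col-0 arrays. They shared 0.03 calls on average. Almost nothing is called where nothing changes, so that count says nothing about the 3 shared calls. The simulated noise was independent between arrays, without the correlation of arrays of a set. Across the 181 genes, which are not independent replicates, the 2 sets of differences correlated at 0.67, against 0.51 in the simulations, and their covariance was 0.179 against 0.0542. The simulated values already hold the sharing of Col-0 arrays, but only with independent noise, so the source of the excess stays open. No check with separate Col-0 arrays for each comparison was made, since 3 arrays cannot be split into groups of 2. Tested directly against each other, the double mutant exceeded pad4-1 in AT4G24340 by 1.33 (SE 0.29, adjusted p = 0.0212), at 5.12 ± 0.30 against 3.79 ± 0.11 (SD, n = 3 each), and in AT2G14290 by 1.08 (SE 0.23, adjusted p = 0.0212). No call remained after quantile normalization or median re-centring, nor without double mutant replicate 1 or 2 or pad4-1 replicate 3. Without pad4-1 replicate 2 there was 1 call and without double mutant replicate 3 there were 5. Over the 10 list members 0 were called over all genes and 2 when adjusted over the list alone, WRKY53 at -0.81 and AT2G04400 at 0.94.

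In the triple mutant under Psm, genes that fell outnumbered those that rose on the deposited scale, an excess that all but vanished after quantile normalization. AT5G39670 fell by 3.77 (SE 0.41, adjusted p = 1.17e-06), from 6.87 ± 0.51 to 3.10 ± 0.10 (SD, n = 3 each). AT3G13950 fell by 3.41 (SE 0.40), AT1G76960 by 2.84 (SE 0.47), and AT5G52760 and AT5G60800, both with a heavy-metal-associated domain, by 2.82 (SE 0.57) and 2.52 (SE 0.30). AT1G09500 fell by 2.70 (SE 0.54), the chaperone gene Hsp70-2 (AT5G02490) by 2.40 (SE 0.32), and UGT76B1 (AT3G11340), whose product glucosylates isoleucic acid and salicylic acid, by 2.36 (SE 0.44). AT4G17470 rose by 3.70 (SE 0.30, adjusted p = 1.96e-08), from 4.76 ± 0.63 to 8.46 ± 0.27 (SD, n = 3 each), and AT1G54010 by 3.56 (SE 0.24, adjusted p = 1.88e-09). AT4G24350 rose by 2.44 (SE 0.32), AT4G24340 by 1.81 (SE 0.29), TUB6 by 1.60 (SE 0.24), the ATP sulfurylase gene APS3 (AT4G14680) by 1.44 (SE 0.25) and AT2G26690 by 1.3 (SE 0.22). PDF1.2 rose by 2.36 (SE 0.68, adjusted p = 0.0101), but the rise was 2.06 (adjusted p = 0.053) without triple mutant replicate 1.

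Of the 10 list members, 6 changed in the triple mutant under Psm, over all genes and adjusted over the list alone, 2 higher and 4 lower. In the salicylic acid lists, UGT76B1, WRKY53 (fell by 1.92, SE 0.27) and GRX480 (fell by 1.32, SE 0.28) were lower, and so was BIP1 (fell by 0.97, SE 0.30). PDF1.2 and the dehydrin gene COR47 (AT1G20440, 0.95, SE 0.36, adjusted p = 0.0488) were higher. COR47 lost its call without Col-0 replicates 1, 2 or 3 (0.81, 1.00 and 1.04) or triple mutant replicates 2 or 3 (0.55 and 0.84) and differed by 1.45 without triple mutant replicate 1, and BIP1 lost its call without Col-0 replicate 2 (-0.85) or triple mutant replicate 1 (-0.77). WRKY22 and WRKY29, transcription factor genes of the pattern-triggered list, differed by -0.28 (SE 0.24) and -0.02 (SE 0.23), and AT5G60390 by 0.04 (SE 0.42). The test called 62 genes, 18 higher and 44 lower. This split was 25 and 40 after median re-centring, 31 and 32 after quantile normalization and 13 and 52 after centring on basal genes, while the median over all 181 genes was -0.13.

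**Figure D1:**
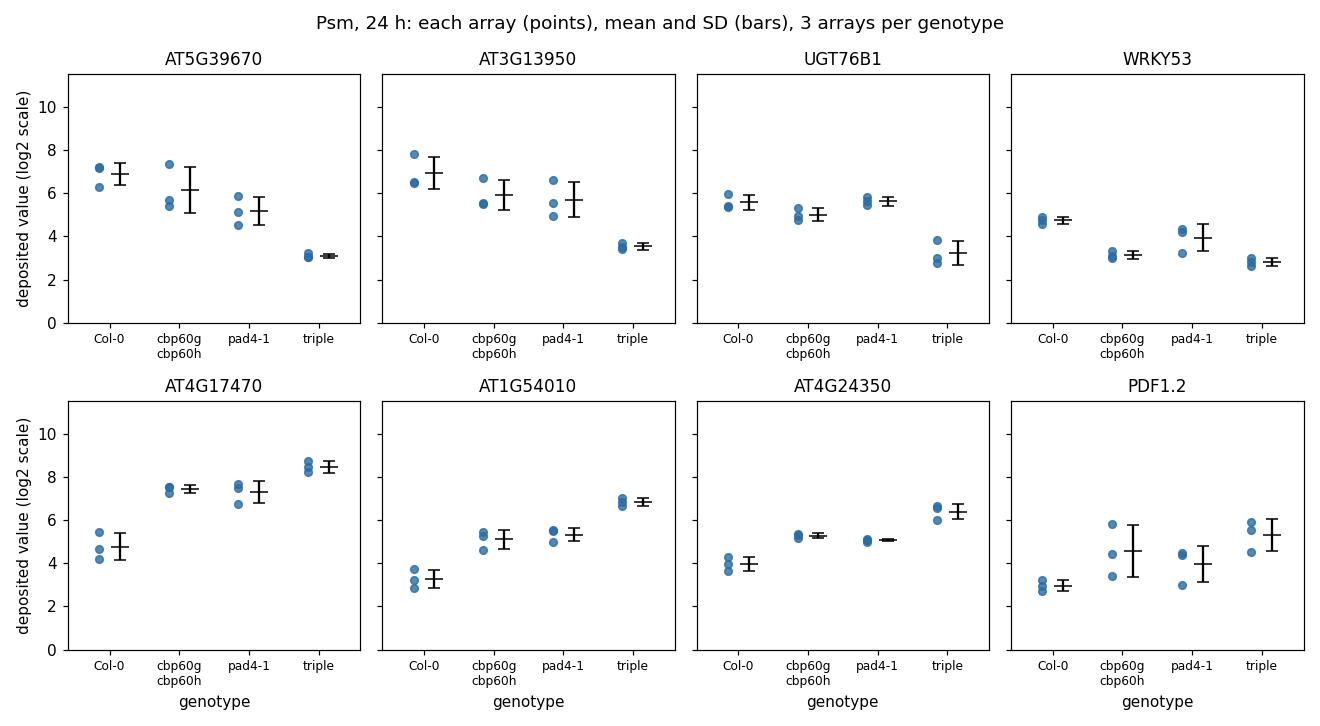
Log2 brightness of selected genes 24 h after Psm in Col-0, the cbp60g cbp60h double mutant, pad4-1 and the cbp60g cbp60h pad4 triple mutant; each point is 1 array, and bars give the mean and SD of 3 arrays. AT5G39670 stands at 6.87 in Col-0 and 3.10 in the triple mutant, and AT4G17470 at 4.76 and 8.46.

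Loss of PAD4 in addition to CBP60g and CBP60h lowered many genes under Psm. Against the double mutant, AT5G39670 fell by 3.04 (SE 0.41, adjusted p = 7.58e-05), AT3G13950 by 2.38 (SE 0.40), AT4G39670, a glycolipid transfer protein-like gene, by 2.36 (SE 0.52), AT5G52760 by 2.27 (SE 0.57) and AT1G76960 by 2.25 (SE 0.47). AT3G28270 rose by 2.03 (SE 0.52), AT1G54010 by 1.73 (SE 0.24), AT2G26690 by 1.32 (SE 0.22), TUB6 by 1.25 (SE 0.24) and APS3 by 1.17 (SE 0.25). Among list members, UGT76B1, GRX480 and BIP1 fell by 1.79, 1.48 and 1.42, 3 of 10 over all genes and adjusted over the list alone, and WRKY53 differed by -0.31 (SE 0.27). With the set as a block COR47 (0.86) was also called (adjusted p = 0.0334). The 56 calls were 14 higher and 42 lower, with a median of -0.15 over all genes. After quantile normalization they were 32 and 29, and after median re-centring 32 and 34.

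Loss of CBP60g and CBP60h in addition to PAD4 lowered an overlapping set of named genes. Against pad4-1, AT1G76960 fell by 2.54 (SE 0.47, adjusted p = 0.00119), UGT76B1 by 2.42 (SE 0.44), AT3G13950 by 2.17 (SE 0.40) and AT5G39670 by 2.06 (SE 0.41). AT5G52760 fell by 2.1 (SE 0.57), with -1.53 (adjusted p = 0.08) without pad4-1 replicate 1 and -1.79 (adjusted p = 0.0623) without triple mutant replicate 3. AT1G54010 rose by 1.51 (SE 0.24), AT4G24350 by 1.33 (SE 0.32), AT4G24340 by 1.16 (SE 0.29) and APS3 by 1.04 (SE 0.25). AT4G17470 rose by 1.16 (SE 0.30), with 0.88 (adjusted p = 0.0504) without pad4-1 replicate 2 and 1.88 after quantile normalization. Of the 10 list members 4 fell, over all genes and adjusted over the list alone: UGT76B1, GRX480 (by 1.46), BIP1 (by 1.15) and WRKY53 (by 1.12). The 39 calls were 11 higher and 28 lower, and 16 and 22 after quantile normalization.

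For some genes the triple mutant lay beyond, or short of, the sum of the 2 separate effects under Psm. GRX480 stood at 8.41 ± 0.24 in Col-0, 8.57 ± 0.17 in the double mutant, 8.55 ± 0.13 in pad4-1 and 7.09 ± 0.68 in the triple mutant (SD, n = 3 each), a departure of -1.62 (SE 0.40, adjusted p = 0.0387) from additive effects. BIP1 departed by -1.59 (SE 0.43), AT1G68620 by -1.49 (SE 0.40) and AT1G11050 by -1.43 (SE 0.32). AT4G17470 departed by -1.51 (SE 0.42), since its rise in the triple mutant was smaller than the sum of the separate rises. AT2G28510 and AT1G29950 departed by 1.23 (SE 0.33) and 1.03 (SE 0.24). Of the 10 list members 2 were called over all genes (3 with the set as a block, where UGT76B1 had an adjusted p of 0.0167) and 3 when adjusted over the list alone. No named departure kept its call in all settings: of 12 arrays left out in turn, GRX480 lost its call without 6, BIP1 and AT4G17470 without 9, AT1G68620 without 8, AT1G11050 and AT1G29950 without 5 and AT2G28510 without 10. After quantile normalization AT4G17470 departed by -0.82 and AT1G11050 by -0.91, neither called. The 10 calls, 2 higher and 8 lower, became 2 and 3 after quantile normalization, 3 and 0 after median re-centring and 0 after centring on basal genes. Left-out arrays moved the count to 5 without Col-0 replicate 1, 0 without Col-0 replicate 3, 1, 0 and 4 without double mutant replicates 1, 2 and 3, 0 and 2 without pad4-1 replicates 1 and 3, and 3, 20 and 0 without triple mutant replicates 1, 2 and 3.

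At 9 h after hrcC, the triple mutant had lower levels than Col-0 of several genes that were also named as falls under Psm. GRX480 fell by 2.27 (SE 0.35, adjusted p = 0.000598), from 7.26 ± 0.55 to 4.99 ± 0.45 (SD, n = 2 each). AT1G76960 fell by 2.93 (SE 0.57), AT5G52760 by 2.50 (SE 0.69), AT5G60800 by 1.79 (SE 0.36) and the EF-hand genes AT5G39670 and AT4G27280 by 2.1 (SE 0.50) and 1.97 (SE 0.52). Hsp70-2 fell by 1.55 (SE 0.39) and CHI by 1.45 (SE 0.35), and AT2G26690 rose by 1.19 (SE 0.27). UGT76B1 differed by -1.81 (SE 0.54, adjusted p = 0.0509 over all genes and 0.0183 over the list alone), so that 1 of 10 list members was called over all genes and 2 when adjusted over the list alone. With the set as a block UGT76B1 was also called over all genes (adjusted p = 0.00918). The 12 calls were 1 higher and 11 lower (1 and 4 after centring on basal genes). There was 1 without Col-0 replicate 1 and 1 without triple mutant replicate 1, and there were 19 without Col-0 replicate 2 and 7 without triple mutant replicate 2. GRX480 was called without each of the 4 arrays, and it was the 1 named change that was. All the others lost their calls both without Col-0 replicate 1, where AT1G76960 differed by -2.02 (adjusted p = 0.174), AT5G52760 by -1.37 and AT4G27280 by -1.14, and without triple mutant replicate 1, where AT1G76960 differed by -2.99 (adjusted p = 0.0596). AT5G52760, AT5G39670, AT4G27280, Hsp70-2 and CHI also lost theirs without triple mutant replicate 2, at -2.26, -2.17, -1.98, -1.68 and -1.49.

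Against the double mutant under hrcC, GRX480 was lower in the triple mutant by a difference of -2.18 (SE 0.35, adjusted p = 0.00101), at 4.99 ± 0.45 against 7.17 ± 0.06 (SD, n = 2 each). It was also lower than in pad4-1, by a difference of -2.51 (SE 0.35, adjusted p = 0.000157), where the level was 7.50 ± 0.38 (SD, n = 2). GRX480 was the 1 gene called in each comparison and the 1 list member of 10, over all genes and adjusted over the list alone. Without triple mutant replicate 1 the difference from the double mutant was -1.86 (adjusted p = 0.0569), and 7 genes were called there with the set as a block. Without pad4-1 replicate 1, 3 genes were called against pad4-1.

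In the double mutant and in pad4-1 at 9 h after hrcC, limma called 0 genes against Col-0. The largest list differences in the double mutant were those of PDF1.2 (1.65, SE 0.83), UGT76B1 (-1.27, SE 0.54) and BIP1 (-0.99, SE 0.37), and in pad4-1 that of PDF1.2 (1.18, SE 0.83), which rest on Col-0 arrays at 7.21 (replicate 1) and 4.66 (replicate 2) for PDF1.2, with 0 of 10 called over all genes or adjusted over the list alone in either line. At an unadjusted p under 0.05 there were 15 genes in the double mutant, 3 higher and 12 lower, and 10 in pad4-1, 3 higher and 7 lower. The fit of all 576 probes called 9 and 6 probes, all lower. With 2 arrays a group, simulated changes of 1 on the log2 scale were recovered in 59.7% of cases in the double mutant's test. There 45 of 181 genes were changed. With fewer changed genes the adjusted threshold is stricter, so recovery can be lower. The double mutant and pad4-1 differed in 0 genes by limma, with 5 at an unadjusted p under 0.05, 0 in the fit of all probes and 0 of 10 list members over all genes or adjusted over the list alone. Without Col-0 replicate 1, 1 gene was called in the double mutant, and without pad4-1 replicate 1, 1 gene differed between the double mutant and pad4-1.

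**Figure D2:**
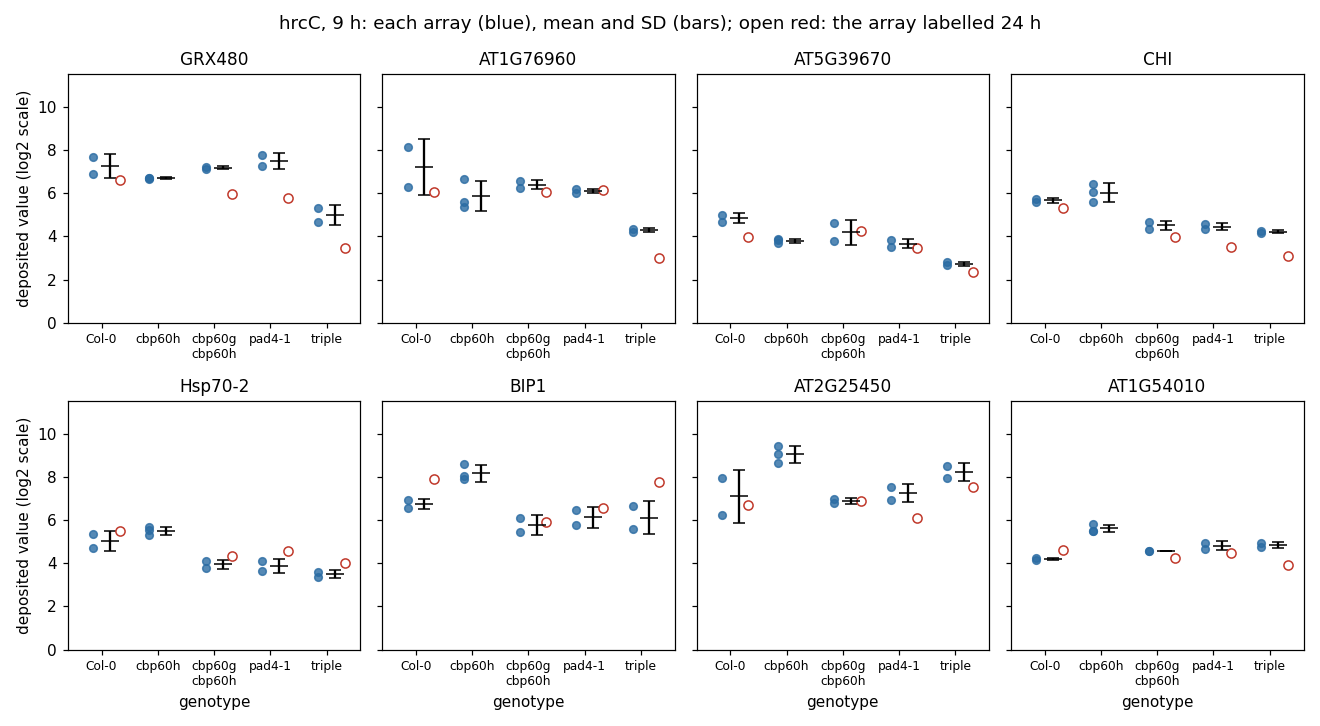
Log2 brightness of selected genes 9 h after hrcC in Col-0, cbp60h, the cbp60g cbp60h double mutant, pad4-1 and the cbp60g cbp60h pad4 triple mutant; each point is 1 array, and bars give the mean and SD of 2 arrays (3 for cbp60h), with the array labelled hrcC 24 h as an open circle. GRX480 stands at 7.26 in Col-0, 7.17 in the double mutant, 7.50 in pad4-1 and 4.99 in the triple mutant.

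The cbp60h mutant differed from Col-0 at 9 h after hrcC in genes of both directions. AT1G54010 rose by 1.41 (SE 0.27, adjusted p = 0.00408), from 4.19 ± 0.04 (SD, n = 2) to 5.61 ± 0.18 (SD, n = 3), and AT1G62480 fell by 1.37 (SE 0.22, adjusted p = 0.000985). AT2G25450, a glucosinolate oxygenase gene, was higher by 1.94 (SE 0.43), AT4G33540 by 1.54 (SE 0.33), BIP1 by 1.42 (SE 0.34), AT4G17470 by 1.27 (SE 0.33), AT1G09500 by 2.04 (SE 0.60), AT2G34810 by 1.57 (SE 0.46) and UGT76E12 (AT3G46660) by 1.27 (SE 0.36). AT2G30930, AT2G43540, AT2G23090 and AT3G48070 differed by -1.29, -1.08, -0.94 and -0.81, and AT1G65500, AT1G67350 and the calmodulin-like gene CML42 (AT4G20780) by -1.66, -1.45 and -1.43. Of 10 list members 2 rose, over all genes and adjusted over the list alone: BIP1 and PDF1.2 (2.31, SE 0.76, adjusted p = 0.0482). PDF1.2 lost its call without Col-0 replicate 2 (1.04) or cbp60h replicates 1 or 2 (1.84 and 2.08) and in the fit of all probes (adjusted p = 0.0565), and differed by 3.59 without Col-0 replicate 1. BIP1 lost its call without Col-0 replicate 1 (1.25) or cbp60h replicate 3 (1.21). The 25 calls were 16 higher and 9 lower, against 13 and 13 after quantile normalization and 10 and 10 after centring on basal genes. The count was 5 without Col-0 replicate 1, 12, 14 and 9 without cbp60h replicates 1, 2 and 3, 13 with the 2 closest cbp60h arrays averaged, and 0 when only the 5 arrays compared were fitted. Of the changes named here, those of AT1G54010 and AT1G62480 were called without each of the 5 arrays. All the others lost their calls without at least 1, and AT1G65500 and AT3G48070 without each of the 5 (-1.85 to -1.29 and -0.86 to -0.75). Without Col-0 replicate 1 AT1G67350, CML42, AT2G23090, AT2G30930, UGT76E12 and AT2G25450 differed by -0.71, -0.73, -0.51, -0.85, 0.78 and 1.08, without Col-0 replicate 2 AT1G67350 differed by -2.20, and without cbp60h replicate 3 AT1G09500 and UGT76E12 differed by 1.17 and 0.76. With the set 3 hrcC arrays added AT1G65500 and AT2G23090 differed by -0.99 and -0.60. On each cbp60h array 282 to 317 probes shared a value with another probe of that array, against 118 to 250 on the 24 other arrays.

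The double mutant, which lacks CBP60g as well, differed from cbp60h in genes of both directions. BIP1 fell by 2.41 (SE 0.34, adjusted p = 0.000183), from 8.17 ± 0.39 (SD, n = 3) to 5.76 ± 0.46 (SD, n = 2). AT3G28540, an AAA-type ATPase gene, fell by 1.99 (SE 0.29), AT2G25450 by 2.15 (SE 0.43), UGT76B1 by 2.08 (SE 0.50) and the calmodulin-like gene AT2G41090 by 2.49 (SE 0.51). AT1G67350 rose by 2.25 (SE 0.45), AT1G65500 by 2.09 (SE 0.53), CML42 by 1.81 (SE 0.46), AT2G43540 by 1.74 (SE 0.32) and AT2G30930 by 1.61 (SE 0.30). Of the 10 list members 3 fell, over all genes and adjusted over the list alone: BIP1, UGT76B1 and AT2G04400 (by 1.36, SE 0.36). With the set as a block AT5G60390 was also called (adjusted p = 0.0469). The 45 calls were 16 higher and 29 lower (21 and 20 after quantile normalization), and 23 without double mutant replicate 1, where UGT76B1, AT2G04400, AT2G41090, AT1G65500 and CML42 lost their calls, at -1.35, -0.75, -1.73, 1.97 and 1.60. BIP1, AT2G25450, AT1G67350, AT1G65500, CML42, AT2G43540 and AT2G30930 were also named in cbp60h against Col-0, with the opposite sign. Against Col-0 itself the double mutant had 0 calls after hrcC. Every difference between the double mutant and cbp60h includes whatever set the cbp60h arrays apart in repeated values. These differences therefore cannot be assigned to the added loss of CBP60g.

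The effect of a mutation was also compared between the treatments, where strain and time differ together. In the triple mutant, the effect on AT4G17470 was larger under Psm at 24 h than under hrcC at 9 h by 3.21 (SE 0.47, adjusted p = 0.000171), and that on AT1G54010 by 2.90 (SE 0.38, adjusted p = 6.69e-05). Under hrcC the triple mutant and Col-0 stood at 3.82 ± 0.26 and 3.33 ± 0.43 (SD, n = 2 each) for AT4G17470. The effects on TUB6 and AT5G21105 differed by 1.46 (SE 0.38) and 1.03 (SE 0.27), and those on AT4G25900 and WRKY53 by -1.84 (SE 0.41) and -1.66 (SE 0.43). These 6 calls were 4 higher and 2 lower (2 and 0 after quantile normalization), with 2 without Col-0 Psm replicate 1, triple mutant Psm replicate 1, Col-0 hrcC replicate 2 or triple mutant hrcC replicate 2, 3 without Col-0 Psm replicate 3 and 10 without triple mutant Psm replicate 2. The 2 largest, AT4G17470 and AT1G54010, were called without each of the 10 arrays and in every alternative. Those on TUB6, AT5G21105 and WRKY53 lost their calls without 8 of the 10, all but Col-0 hrcC replicate 1 and triple mutant Psm replicate 2, with 1.17 to 1.72, 0.90 to 1.17 and -1.75 to -1.52, and that on AT4G25900 without 4. The effect on AT5G21105 differed by 0.63 after centring on basal genes. WRKY53 was the 1 list member called, over all genes and adjusted over the list alone.

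In pad4-1, 1 gene had a different effect in the 2 treatments, AT4G17470, by 2.16 (SE 0.47, adjusted p = 0.0364), and 0 list members did. That call was lost without Col-0 hrcC replicate 1, pad4-1 hrcC replicate 1 or 2, Col-0 Psm replicate 1 or 3, or pad4-1 Psm replicate 1 or 3, and after quantile normalization (2.06, adjusted p = 0.245), while 2 genes were called without Col-0 Psm replicate 2. For the double mutant limma called 0 genes, with 23 at an unadjusted p under 0.05 and 2 in the fit of all probes, and list members gave 0 over all genes and 3 when adjusted over the list alone. There, 1 gene was called without Col-0 hrcC replicate 1 or double mutant Psm replicate 1, and 4 without Col-0 Psm replicate 2.

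The arrays labelled hrcC 24 h are 1 for each genotype, so the genotypes were not tested against each other at that time. In these, GRX480 was at 3.46 in the triple mutant and 6.59 in Col-0, a difference of -3.12, and AT1G76960 was at 3.02 and 6.04, a difference of -3.02. CHI differed by -2.23, AT5G52760 by -1.89, AT5G39670 by -1.65, Hsp70-2 by -1.50, AT4G27280 by -0.97 and AT2G26690 by 0.69. All 12 genes called in the triple mutant at 9 h had a difference of the same sign here. The share of all 181 genes that kept their sign was not computed. Other genes, chosen after their values were seen, differed in the triple mutant with the opposite sign to that at 9 h. Their 9 h differences were not called, so no reversal of an effect is shown. AT4G17470 differed by -1.37 (0.49 at 9 h), AT1G54010 by -0.71 (0.66 at 9 h) and AT2G41090 by 0.60 (-1.40 at 9 h). Also chosen afterwards, PDF1.2 differed by 4.00 in the double mutant and 3.54 in pad4-1. In the double mutant UGT76B1 and BIP1 differed by -2.30 and -1.99. Differences over 1 were 17 higher and 12 lower in the double mutant, 7 and 8 in pad4-1, and 15 and 25 in the triple mutant. Across the 181 genes, which are not independent replicates, the difference between mutant and Col-0 correlated with that at 9 h at 0.54 for the triple mutant, 0.49 for the double mutant and 0.30 for pad4-1.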

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

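The tests by regrouping the Psm arrays were written before their results were seen, and the 5 other tests given here were chosen afterwards. The 3 cbp60h arrays stood apart from the other arrays after hrcC. A separate batch of arrays is a candidate explanation that the values do not exclude. At least 282 probes on each cbp60h array shared a value with another probe of that array. On any of the 24 other arrays at most 250 did. This count is also what sets the cbp60h arrays apart, so it adds no separate support for a batch. Loss of CBP60h with the same effect in every genotype was tested on the 25 genes called in cbp60h, whose median effect was 1.27. In the double and triple mutants against pad4-1 their median effect was 0.0332 (bootstrap over genes -0.184 to 0.164). That contrast also holds loss of CBP60g and, in the double mutant, an intact PAD4. The 25 genes were picked in these same cbp60h arrays, which can enlarge the 1.27. So the genes did not move that way as a set there, but this does not settle whether loss of CBP60h acts alike everywhere. Such an effect, an effect that needs an intact CBP60g, and a batch all stay open. The 25 differences, those of AT1G54010 and BIP1 among them, therefore cannot be assigned to the mutation.

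The hrcC arrays of set 3 carry a 24 h label where sets 1 and 2 carry 9 h. If these leaves were harvested later, set 3 could lie farther from sets 1 and 2 under hrcC than under Psm. The mean ratio of distances was higher under hrcC by 0.210 (exact permutation p = 0.229, n = 4 genotypes), which cannot tell. The permutation did not pair the 2 ratios of a genotype. With 4 genotypes a paired permutation could not reach a p under 0.05. By gene, limma called 8 differences between set 3 and the other sets under hrcC and 0 under Psm (42 and 31 at an unadjusted p under 0.05), and 2 genes differed between the treatments in this respect, AT2G23090 (-0.92) and Hsp70-2 (1.16).

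Falls outnumbered rises in the triple mutant under Psm, 44 to 18. A lower overall level of the triple mutant arrays, large enough to explain falls with a median of -1.56, is argued against by 14 basal genes. Their median difference was -0.0867 (bootstrap over genes, not arrays, -0.161 to 0.120). They were chosen after values had been seen, and 1 of them, TUB6, was called higher (by 1.60). A smaller shift stays open, and it could add to the excess of falls. The median over all genes was -0.13, which by itself leaves little room for a shift near -1.56, so the basal genes add little. Over all probes the array medians were 4.07, 4.38 and 4.23 in the triple mutant against 4.48, 4.44 and 4.41 in Col-0. For a scaling that differs from the deposited one the tests cannot tell: the smallest excess of falls was 1.59 percentage points, after quantile normalization, which makes the arrays equal in distribution and so can itself remove an excess.

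Regrouping the 6 Psm arrays of 2 genotypes gives 10 splits, too few for a share under 0.05. In each of these 6 comparisons 1 split, the real one, called as many genes as were reported. The real split called 12 genes in the double mutant, 5 in pad4-1 and 62 in the triple mutant against Col-0, and at most 1, 0 and 5 were called in any other. For the triple mutant against the double mutant, the triple mutant against pad4-1 and the double mutant against pad4-1 the counts were 56, 39 and 2, and at most 7, 7 and 0 in any other split. For the departure from additive effects, 11 of 100 regroupings of the 12 arrays called at least the real 10 genes, and at most 44 were called in any other. A regrouping carries the differences between genotypes into this contrast, 62 genes between the triple mutant and Col-0 among them, and parts arrays of a set, so these counts point to structure among the arrays and decide nothing about chance. Whether chance gave the departures of GRX480, BIP1 and the 8 other genes stays open.

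Between the treatments, the mutation effect differed in 1 gene in pad4-1, AT4G17470 (2.16), and in 6 genes in the triple mutant: AT1G54010 (2.90), AT4G17470 (3.21), TUB6 (1.46), AT5G21105 (1.03), WRKY53 (-1.66) and AT4G25900 (-1.84). Probes without a gene name were also called in the fit of all probes: 35 in cbp60h, 9 in the double mutant, 6 in pad4-1 and 26 in the triple mutant after hrcC, and 37, 19 and 170 in the double mutant, pad4-1 and the triple mutant after Psm. They were not analysed here by gene.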

How the results depend on the processing

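The fit of all probes, the centring on basal genes and the 2 treatments of the cbp60h arrays were chosen after results had been seen, and the other settings before. No named difference turned direction in any setting. The cause was not tested for the counts that moved by more than 1.5 times, which follow. Set number as a block: triple against double mutant after hrcC 7 for 1, and of 116 named changes only that of AT4G25900 in pad4-1 was lost. Median re-centring: that hrcC comparison 2, double mutant against pad4-1 under Psm 0, departure from additive effects 3, pad4-1 treatment difference 0. Quantile normalization: double mutant against pad4-1 0, departure 5, treatment difference 0 in pad4-1 and 2 in the triple mutant. Without the dimmest genes, which removed 8 of the 116: under Psm 6 in the double mutant, 3 in pad4-1 and 1 between them. Set 3 hrcC arrays added with a block: after hrcC 6 in the double mutant, 24 in the triple mutant, and triple mutant 23 against double mutant and 8 against pad4-1; under Psm 8 in pad4-1, 5 double mutant against pad4-1, departure 17; treatment differences 7, 2 and 19 in the double mutant, pad4-1 and the triple mutant. The same without a block: after hrcC 23 in the triple mutant, 16 against the double mutant and 3 against pad4-1; under Psm 4 and departure 1; treatment differences 3, 2 and 13. All probes: after hrcC 57 in cbp60h, 9 in the double mutant, 166 between these, 6 in pad4-1, 38 in the triple mutant and 4 triple mutant against pad4-1; under Psm 49, 24 and 236 in the double mutant, pad4-1 and the triple mutant, triple mutant 213 against double mutant and 149 against pad4-1, 25 double mutant against pad4-1 and departure 36; treatment differences 2, 0 and 34; Col-0 between treatments 197. These rises follow in part from the larger number tested. Centred on basal genes: triple mutant after hrcC 5, 3 against the double mutant; under Psm 23 in pad4-1, 5 double mutant against pad4-1, departure 0; treatment differences 0 in pad4-1 and 13 in the triple mutant. With 2 cbp60h arrays averaged, cbp60h 13. With cbp60h arrays left out: triple against double mutant after hrcC 2, departure 2, pad4-1 treatment difference 0. Only the groups compared: cbp60h 0, triple mutant after hrcC 7, 6 against the double mutant and 13 against pad4-1; under Psm 7 in the double mutant, 0 double mutant against pad4-1, departure 4; pad4-1 treatment difference 0. Trend and robust variance moved no count by that much.

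Leaving out 1 array at a time gave these ranges. After hrcC: cbp60h 5 to 25, double mutant 0 to 1, double mutant against cbp60h 23 to 38, pad4-1 0 to 0, triple mutant 1 to 19, triple against double mutant 0 to 1, triple mutant against pad4-1 1 to 3, double mutant against pad4-1 0 to 1. Under Psm: double mutant 7 to 14, pad4-1 3 to 5, triple mutant 47 to 62, triple against double mutant 49 to 60, triple mutant against pad4-1 29 to 47, double mutant against pad4-1 0 to 5, departure 0 to 20. Treatment differences: 0 to 4, 0 to 2 and 2 to 10 in the double mutant, pad4-1 and the triple mutant, and 41 to 59 in Col-0. The mean over probes of a gene was not run, as each gene has 1 probe.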

Other observations

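The gene groups and the single genes in this part were chosen after the values had been seen. The adjusted p of a set therefore describes these data and is no independent test of the set. Of 5 genes for calcium-binding EF-hand proteins 4 fell in the triple mutant under Psm: AT5G39670 by 3.77, AT2G41090 by 1.86, AT2G41410 by 1.64 and AT4G27280 by 1.40, with CML42 at -1.01 (adjusted p = 0.0653). With the set as a block CML42 was also called (adjusted p = 0.0332), as were all 5 after centring on basal genes. The median of these 5 genes was -1.64, and a test of the set against all other genes gave an adjusted p of 0.0357, or 0.188 with the correlation among the genes estimated from the data. Against the double mutant all 5 fell, with a median of -1.67 (adjusted p = 0.0115, or 0.103). Against pad4-1, 3 of the 5 fell, with a median of -1.13, and the set had an adjusted p of 0.0635 (or 0.258). That test is open to the scaling: after median re-centring, quantile normalization and centring on basal genes its adjusted p was 0.0357, 0.00953 and 0.0208, while 1, 2 and 1 of the 5 genes were called. After hrcC, 2 of the 5 fell in the triple mutant (1 after centring on basal genes), with a median of -1.40 (adjusted p = 0.00481, or 0.0674). All 5 differences were negative in these comparisons under each scaling.

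Also in the triple mutant under Psm, the sulfite reductase gene SIR (AT5G04590) rose by 1.07 (SE 0.25, adjusted p = 0.00232). The AAA-type ATPase genes AT3G28540 and AT3G28510 fell by 2.33 (SE 0.26) and 1.72 (SE 0.31), and the berberine bridge enzyme-like gene AT1G26380 by 1.38 (SE 0.31). CHI fell by 2.26 (SE 0.28, adjusted p = 4.72e-06), from 8.23 ± 0.03 to 5.97 ± 0.23 (SD, n = 3 each). The aspartyl protease genes AT3G51330 and AT2G39710 fell by 1.47 (SE 0.33) and 1.3 (SE 0.20), 2 of 4 such genes. Of 3 peroxidase genes 0 changed, of 4 WRKY genes 2 fell, and of 7 glycosyltransferase genes 2 rose and 1 fell. Of 5 protein folding genes, Hsp70-2 and BIP1 fell in the triple mutant (1 fell after quantile normalization, and 3 after centring on basal genes or with the set as a block), and the set did not pass (adjusted p = 0.133, or 0.326). In Col-0, AT3G09440, Hsp70-2, AT2G29500 and AT5G48570 were higher after Psm at 24 h than after hrcC at 9 h, by 1.09, 1.08, 1.81 and 1.3, while BIP1 was lower (adjusted p = 0.594 for the set). These 4 higher and 1 lower were 3 and 1 after median re-centring, 1 and 1 after quantile normalization and 4 and 0 after centring on basal genes.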
